A study of Populus tremula x Populus alba with 14 samples.

How the data were processed

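RNA sequencing libraries were analysed from the bark of hybrid poplar (Populus tremula x Populus alba, clone INRA 717-1B4), a tree widely used in wood and bark research. Outer bark samples were described in the labels as phellem (cork) with phellogen (the meristem that makes it), and inner bark samples as secondary phloem with vascular meristem. Stems were old (6 to 8 mm in diameter) or young (4 to 5.5 mm). There were 4 libraries each of old outer and old inner bark and 3 each of young outer and young inner bark, 14 in all. Groups and replicate numbers were taken from the sample labels.

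The authors deposited a table of read counts per gene for all 14 libraries, not normalized, per the file headers and the values, which were whole numbers with a different total in each library. The submitters' processing notes name CASAVA, Trimmomatic, TopHat, Bowtie, Cufflinks, DESeq, edgeR and HTSeq without versions, and the role of each is not given in the sources used here. The genome build is also not given in the sources used here. The protocol was unstranded per the labels' protocols, so reads of a gene and of an overlapping antisense gene cannot be told apart. Reads of near-identical copies may have been split by the authors' counting. The authors' deposited tables of their own layer comparisons hold, per the file headers, log2 fold changes and log2 CPM. Those deposited tables also hold p-values and adjusted p-values from DESeq and edgeR. Their log2 fold changes were negative where the outer bark columns were higher. Their raw count columns equalled the count table in 100% of the values compared. Their 14 normalized columns were not used here. No per-sample column was left without a sample (0 columns).

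Total counts were between 11944485 and 15980636 per library. Of 41335 genes in the table, 27673 passed edgeR's expression filter (filterByExpr) and were tested, and 13662 were removed. Counts were scaled with TMM factors and fitted with edgeR 4.0.16 under R 4.3.3, by the quasi-likelihood F test with robust dispersions and 4 group means, which left 10 residual degrees of freedom. The layer contrast was outer minus inner within each age, the age contrast was old minus young within each layer, and the interaction was the old layer contrast minus the young one. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. CPM values were computed with the TMM-scaled library sizes, and fold changes are those of the fitted model.

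The titles number the stems within each age, so the outer and inner libraries of a number may come from one tree. This was checked before the calls of the fits were compared. The deviations of the outer and inner libraries of a number from their group means correlated across genes at 0.82, 0.62, 0.73 and 0.60 for old stems 1 to 4 and at 0.82, 0.74 and 0.76 for young stems 1, 2 and 4. Every library correlated best with its own number in the other layer. The numbers were therefore taken to pair the layers within an age, and a fit with the number as a block (5 residual degrees of freedom) is given beside the layer and interaction results. A numbered stem is called a tree below, although the labels do not state this. The fit of group means counts the layers of a tree as independent libraries. Its 10 residual degrees of freedom are therefore overstated for the age contrasts, whose p-values may be too small. The layer contrasts and the interaction lie within trees, so its p-values for them include the spread between trees and may be too large. One young inner library has the leading number 9 in its title where its partner has 20, while the other pairs have consecutive numbers. The labels do not say that libraries of different numbers came from separate trees, so p-values measure the spread between these samples.

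The files pair no identifier with a gene name: the symbol column repeated the identifier in 100% of rows. The 22 gene lists fixed before the data were examined (cork, cell wall, phloem, cambium and other processes) were defined by names and could not be filled. Their tests are void and are not reported. The rule for named genes, also fixed before the data were examined, took the largest fold changes in each direction among genes past the threshold, with a mean log2 CPM of at least 3 and no overlap between the CPM values of the 2 groups compared. Because no names were paired with identifiers, at most 2 identifiers per direction are printed for a contrast, and its condition on names could not be applied. Gene groups are therefore described by where their members were higher.

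The tests, samples, covariates and most alternatives were fixed before the data were examined. The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma 3.58.1 (voom), other count filters, only the groups compared, the block and leaving out each library. The other alternatives, added after seeing the data, were the block as a random effect, settings of the blocked fit, leaving out each tree, and leaving out tree 1 of both ages. The sets of genes called at one age were tested at the other with camera and fry. Shares of counts were compared by exact permutation tests, 2-sided.

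The fits were tested on simulated data with 200 changed genes per contrast. The fit of group means recovered 69% of genes changed 4-fold between layers in old stems, 50% in young stems, 31% for the interaction, 58% for age in outer bark and 45% for age in inner bark. At 2-fold it recovered 17%, 3%, 1%, 9% and 5% in the same order. The blocked fit recovered 97%, 98% and 83% at 4-fold for the layer contrast in old stems, in young stems and the interaction, and 78%, 85% and 51% at 2-fold. False calls were 7.9%, 11.2% and 13% of the blocked calls, above the nominal 5%. They were between 1.9% and 8.6% of the calls in the fit of group means. The data simulated for the fit of group means held no tree effects, unlike those for the blocked fit. Its rates of recovery and false calls therefore leave out the correlation between the layers of a tree.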

Results

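Transcript levels were measured by RNA sequencing in the outer and inner bark of hybrid poplar stems at 2 ages. Outer bark held the phellem, the cork tissue, and the phellogen that produces it. Inner bark held the secondary phloem, which conducts sugars, and the vascular meristem. The mean total count per library was 14759552 ± 1218357 in old outer bark (SD, n = 4) and 12822476 ± 589674 in old inner bark (SD, n = 4). It was 14925473 ± 1047838 in young outer bark (SD, n = 3) and 14200459 ± 1026613 in young inner bark (SD, n = 3). Between 30278 and 32847 genes had at least 1 count in a library. No 2 libraries of a group agreed within sampling noise. The 100 most abundant genes took 11.8% ± 1.7 of the counts in old outer, 12.3% ± 1.5 in old inner, 9.3% ± 0.8 in young outer and 9.7% ± 0.4 in young inner bark (SD, n = 4, 4, 3 and 3).

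Stem age separated the libraries along the first principal component, which held 47.9% of the variance. Old libraries lay between -186.7 and -6.5 and young libraries between 48.3 and 151.8. Within each age, the outer library of a tree lay above its inner library on the second component, which held 20.2%. Both libraries of old tree 1 stood apart from the other old libraries of their own layer on that component, at -55.6 (outer) and -118.8 (inner).

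**Figure D1:**
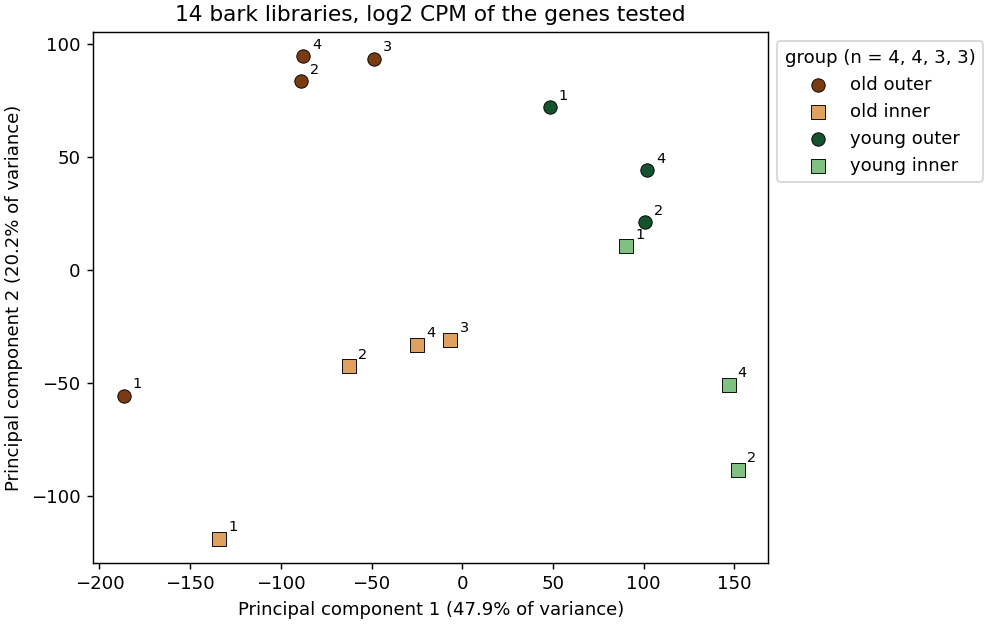
Libraries on the first (x axis) and second (y axis) principal components of log2 CPM, without units; each point is 1 library, coloured by group and numbered by tree. Old libraries lie between -186.7 and -6.5 and young ones between 48.3 and 151.8 on the first component.

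The comparison of outer with inner bark in old stems asks which transcripts distinguish cork and its meristem from the phloem side of the bark. In old stems 1469 genes were higher in outer bark and 1402 were higher in inner bark, 2871 of 27673 tested. The outer-higher genes differed by a median of 3.36-fold, 625 of them by at least 4-fold and 177 by at least 16-fold in fitted values. The median inner level of these 177 genes was at most 0.0837 CPM in the old trees, so their fold changes are imprecise. The inner-higher genes differed by a median of 3.87-fold, 669 by at least 4-fold and 31 by at least 16-fold. No gene had at least 10 counts in each library of one layer and no count in the other, in either direction and at either age (0 genes).

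Potri.018G152600 was at 48.1 ± 21.6 CPM in old outer and 2.74 ± 1.06 CPM in old inner bark (SD, n = 4 each), a log2 fold change of 4.14 ± 0.64 (SE; edgeR adjusted p = 0.00263). Potri.013G007000 was at 28.6 ± 18.1 CPM in old outer and 0.975 ± 0.577 CPM in old inner bark (SD, n = 4 each), with a log2 fold change of 4.86 ± 1.15 (SE; edgeR adjusted p = 0.019). Its call was lost without old inner replicate 2 or 3, with adjusted p up to 0.0555 over all alternatives. On the inner side, Potri.016G104300 was at 1.51 ± 1.73 CPM in old outer and 42.3 ± 30.6 CPM in old inner bark (SD, n = 4 each), a log2 fold change of -4.81 ± 0.90 (SE; edgeR adjusted p = 0.00657), which was -6.01 without old outer replicate 4. Potri.010G196300 was at 2.62 ± 1.58 CPM in old outer and 44.3 ± 32.1 CPM in old inner bark (SD, n = 4 each), a log2 fold change of -4.08 ± 0.87 (SE; edgeR adjusted p = 0.0122), which was -3.47 without old inner replicate 2.

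With trees as blocks, 5207 genes were higher in old outer and 5654 in old inner bark, 10861 in all. They held 2870 of the 2871 genes called without the block, in the same direction. Which layer had more blocked calls depended on the scaling, with 5481 genes higher in outer and 5303 in inner bark under RLE factors. DESeq2 called 4509 genes, and 1806 passed in a fit of the old libraries alone. Without the block, the count was 1802 without old outer replicate 2, 1685 without old outer replicate 4 and 1554 without old inner replicate 3. It rose to 5216 without tree 1 of both ages. The authors' deposited table for old stems lists 30947 genes and gives an edgeR adjusted p below 0.05 to 1920 genes higher in outer and 1478 higher in inner bark. In the authors' deposited table, DESeq did so for 971 and 717 genes.

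In young stems the same comparison gave 90 genes higher in outer and 17 higher in inner bark, of 27673 tested. An unadjusted p below 0.05 was found for 3595 genes, against 1384 expected by chance. The outer-higher genes differed by a median of 2.79-fold and the inner-higher genes by 2.69-fold. With trees as blocks, 5148 genes were higher in young outer and 4071 in young inner bark, 9219 in all, and they held all of the former 90 and 17 genes in the same direction. Which layer had more blocked calls depended on the scaling: RLE factors gave 4515 genes higher in outer and 5107 in inner bark, and DESeq2 with the block gave 3960 and 4127. The blocked count also moved widely when single trees were left out, over a range given with the processing alternatives below. The young count without the block was unstable: RLE scaling gave 37 genes higher in outer and 14 in inner bark, DESeq2 called 1297 genes and the young libraries alone gave 0, with 5265 genes at an unadjusted p below 0.05. Leaving out either library of young tree 2 or 4, or old outer replicate 4, which shares the estimate of the spread, also gave 0. The count rose to 215 without old outer replicate 1, 224 without young outer replicate 1 and 235 without young inner replicate 1. Without tree 1 of both ages it was 1504. The authors' deposited table for young stems gives an edgeR adjusted p below 0.05 to 877 genes higher in outer and 370 higher in inner bark.

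**Figure D2:**
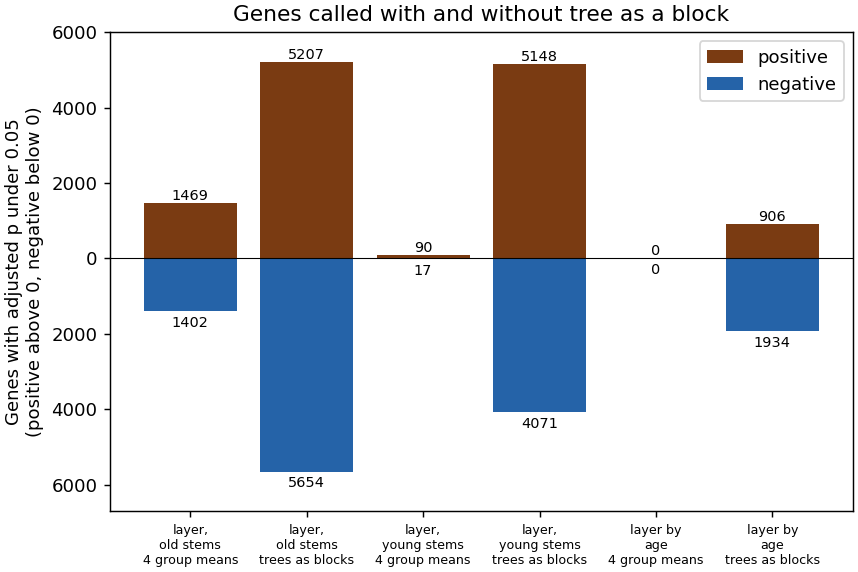
Genes with an adjusted p below 0.05 (y axis, number of genes; bars above 0 positive, below 0 negative) for the layer contrast in old stems, in young stems and their difference, with 4 group means or with trees as blocks. In young stems the bars are 90 and 17 genes without the block and 5148 and 4071 with it, or 4515 and 5107 with it under RLE factors.

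Most genes called between the layers in old stems had a fold change of the same sign in young stems, which were separate libraries. Of the genes higher in old outer bark, 97.0% had a positive young log2 fold change, with a median of 1.22 against 1.75 in old stems. Of the genes higher in old inner bark, 97.2% had a negative young log2 fold change, with a median of -0.70 against -1.95 in old stems. The choice of these genes in old stems favours larger values there, so the smaller young medians do not by themselves show a weaker layer difference. Among genes called at both ages, 82 were higher in outer bark (4.78 expected for independent lists) and 13 higher in inner bark (0.861 expected), and 0 were called in opposite directions. With trees as blocks, 89.3% of the old outer-higher and 84.9% of the old inner-higher genes had the same sign in young stems, 3330 were higher in outer bark at both ages (969 expected), 2457 higher in inner bark at both (832 expected), and 241 were called in opposite directions. Across genes, which are not independent replicates, the fold changes of the ages correlated with a Pearson r of 0.717 and a Spearman rho of 0.629. As a set, the old outer-higher genes were higher in young outer bark than other genes (camera p = 3.71e-78 with a preset correlation and p = 0.000584 with an estimated correlation). The old inner-higher genes were lower there (camera p = 1.25e-52 preset and p = 0.00518 with an estimated correlation).

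The outer-higher genes of old stems took 5.01% ± 0.718 of the counts in young outer and 2.20% ± 0.13 in young inner bark (SD, n = 3 each). The inner-higher genes took 3.78% ± 0.404 in young outer and 5.92% ± 0.399 in young inner bark (SD, n = 3 each). Each difference had an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. These permutations left out the pairing of the layers of a tree, and swaps within 3 trees are too few for a p below 0.05. The named genes kept their direction in young stems without passing the test of group means. Potri.018G152600 was at 39.6 ± 22.1 CPM in young outer and 6.30 ± 4.51 CPM in young inner bark (SD, n = 3 each; edgeR adjusted p = 0.105, and 0.00882 with trees as blocks). Potri.016G104300 was at 4.59 ± 2.01 CPM in young outer and 83.96 ± 53 CPM in young inner bark (SD, n = 3 each; edgeR adjusted p = 0.0828, and 0.000328 with trees as blocks).

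**Figure D3:**
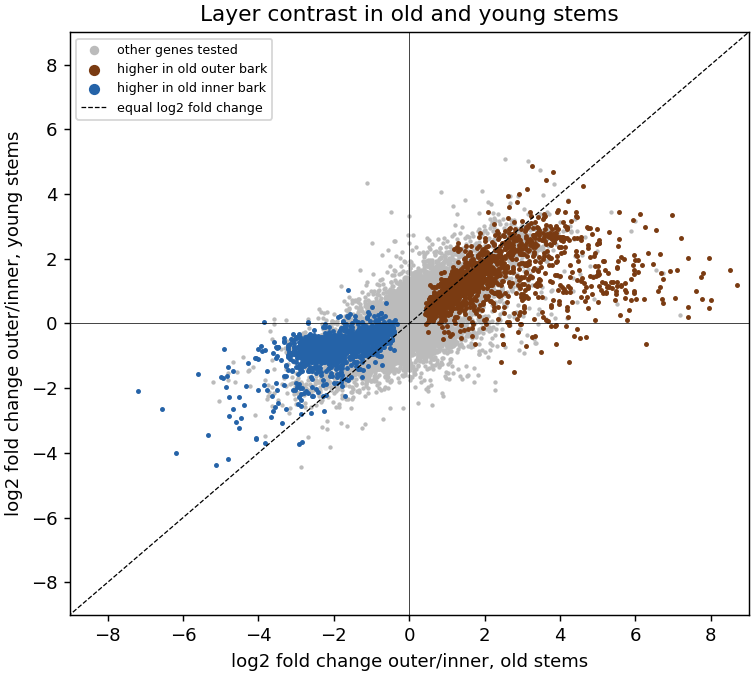
Log2 fold change of outer over inner bark in old stems (x axis) and young stems (y axis); each point is 1 of 27673 genes, coloured where it passed the test in old stems, and the dashed line marks equal values. Of the genes higher in old outer bark, 97.0% lie above 0 on the y axis, and of those higher in old inner bark, 97.2% lie below 0.

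Whether the layers differed more at one age was tested by the interaction. With group means, edgeR called 0 genes and DESeq2 called 42. In edgeR 1226 genes had an unadjusted p below 0.05, where 1384 would be expected by chance if all libraries were independent. This fit leaves out the pairing of the layers of a tree, so its interaction p-values may be too large. The low number is therefore no evidence against an interaction. The blocked fit had 7387 genes at an unadjusted p below 0.05. With trees as blocks, 2840 genes passed: the layer difference (outer minus inner) was more negative in old stems for 1934 genes and more positive for 906. The 1934 genes had a median layer log2 fold change of -1.03 in old and -0.09 in young stems, and 747 of them were among the old inner-higher genes. The 906 genes had medians of 0.65 in old and -0.29 in young stems, and 235 of them were among the old outer-higher genes. Both sets were chosen for this difference in the same libraries, so gaps in these directions between the medians follow from the choice. The split depended on the scaling: RLE factors gave 1553 negative and 1334 positive genes. Without young tree 2 or young tree 4 the blocked count was 781 and 896, and without old tree 2 it was 1283. In simulated data 13% of the blocked interaction calls were false.

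Old and young stems were also compared within each layer. In outer bark 2353 genes were higher in old stems, by a median of 1.87-fold, and 3740 were higher in young stems, by a median of 4.26-fold, 6093 in all. In inner bark 3916 genes were higher in old stems, by a median of 1.93-fold, and 4132 were higher in young stems, by a median of 3.94-fold, 8048 in all. Which age had more calls in inner bark depended on the processing: the stricter CPM filter gave 4390 genes higher in old and 3878 in young stems, and RLE factors gave 3375 and 4453. At least 4-fold differences were found for 256 genes higher in old and 1981 higher in young outer bark, and for 480 and 2038 genes in inner bark. Both layers called 4631 genes, of which 2005 were higher in old stems in both and 2622 higher in young stems in both (333 and 558 expected for independent lists). The layers of a tree are not independent libraries, and the numbers expected for independent lists leave out the trees they share. The fit of group means also counts these layers as independent, so its age p-values, those of named genes included, may be too small. Fits of each layer alone gave 3779 genes in outer and 5505 in inner bark. With the tree as a random effect the counts were 5613 and 7043.

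Potri.010G002600 was at 386.4 ± 540 CPM in old outer and 5.15 ± 2.31 CPM in young outer bark (SD, n = 4 and 3; log2 fold change 6.23 ± 1.44 SE, edgeR adjusted p = 0.012). Old outer replicate 1 alone was at 1196 CPM, and the call was lost without young outer replicate 4 (adjusted p = 0.0524; 5.63e-08 to 0.105 over all alternatives). Without old outer replicate 1 its log2 fold change was 4.56. Potri.006G238600 was at 91.4 ± 42.5 CPM in old outer and 1.65 ± 2.30 CPM in young outer bark (SD, n = 4 and 3; log2 fold change 5.75 ± 1.22 SE, edgeR adjusted p = 0.00812), and its log2 fold change was 8.06 without young outer replicate 1. Both were also higher in old inner bark, with log2 fold changes of 6.99 ± 1.501 and 5.94 ± 1.24 (SE; edgeR adjusted p = 0.00601 and 0.00524). These were 5.23 without old inner replicate 1 and 8.44 without young inner replicate 1. Potri.009G087200 was at 0.752 ± 0.603 CPM in old outer and 62.7 ± 37.3 CPM in young outer bark (SD, n = 4 and 3; log2 fold change -6.34 ± 1.10 SE, edgeR adjusted p = 0.00333), and its log2 fold change was -7.02 without old outer replicate 3. Potri.002G119300 was at 3.20 ± 1.85 CPM in old outer and 187.5 ± 155 CPM in young outer bark (SD, n = 4 and 3; log2 fold change -5.87 ± 1.09 SE, edgeR adjusted p = 0.00459), and its log2 fold change was -5.28 without young outer replicate 2. In inner bark these were lower in old stems by log2 fold changes of -3.95 ± 0.96 and -3.58 ± 0.99 (SE; edgeR adjusted p = 0.0104 and 0.019).

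The age counts rested in part on single libraries. The outer bark count was 3115 without young outer replicate 2, 2715 without young outer replicate 4 and 3779 in a fit of the outer libraries alone. The inner bark count was 4974 without young inner replicate 2 and 4554 without young inner replicate 4. Without tree 1 of both ages it rose to 10463 genes in outer and 13122 in inner bark.

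**Figure D4:**
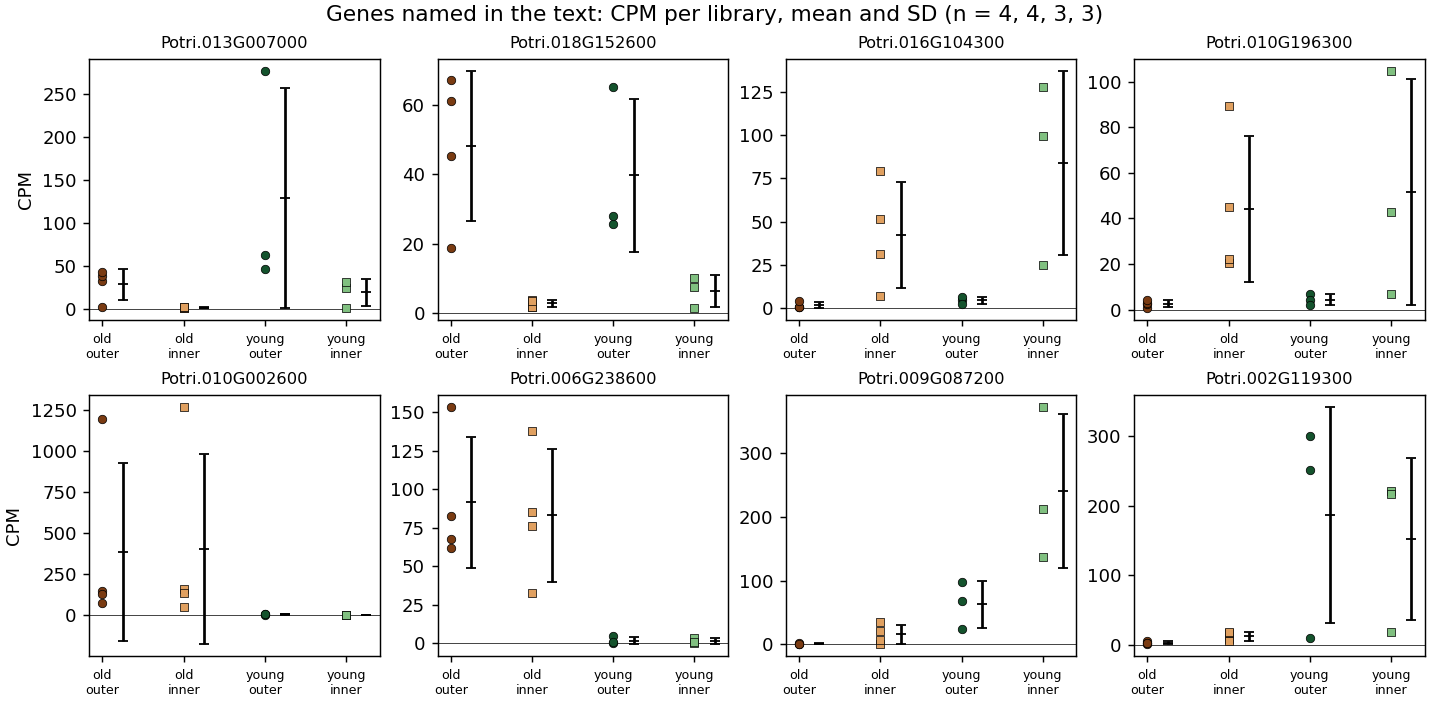
CPM (y axis, linear) of the 8 named genes in each library (points) of the 4 groups (x axis), with the group mean and SD beside the points. Potri.016G104300 lies at 1.51 CPM on average in old outer and 42.3 CPM in old inner bark, and Potri.010G002600 reaches 1196 CPM in old outer replicate 1.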

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

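All tests of explanations in this part were chosen after the results they concern had been seen, and the rules for tissue carry-over, depth and scaling were changed after a first result. Library measures and CPM of the named genes were examined for 1 value far from the rest in old outer and old inner bark. Of 36 sets of 4 values, 9 held one, where chance gives about 1 in 20 for normal values. The 36 sets share the same libraries and are not independent, and most of the 9 concern old replicate 1, so the 2 rates cannot be compared directly. Old outer replicate 1 was apart in the share of its most abundant gene (0.805%), on principal component 2 (-55.6) and on component 3 (-89.2). Old inner replicate 1 was apart on components 2 (-118.8) and 3 (-30.6). Potri.010G002600 reached 1196 CPM in old outer replicate 1 and 1271 CPM in old inner replicate 1. Potri.016G104300 was at 4.107 CPM in old outer replicate 4, and old inner replicate 4 had the lowest total count, 11944485. A test of the difference between ages found 2840 genes whose layer contrast differed with trees as blocks.

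The layer difference of tree 1 was weak on the outer side at both ages. Genes at least 2.5 log2 units higher in outer bark in the other 6 trees were at a median of 23% of their outer level in the inner bark of old tree 1 (quartiles 15.2 and 39.7) and 32.3% in young tree 1 (quartiles 27.4 and 42.4), against 3.1% to 12% in the other 5 trees, while inner markers in outer bark were at 13.9% and 11.4%, within the 5.9% to 28.9% of the others. Depth is argued against in both, since those of the other 5 trees whose inner totals were lower or at most 2 percent higher reached no more than 12% in either comparison, below both lower quartiles. Young tree 1 had the highest inner total of all trees, 15311271, so its inner library was not shallow in the first place. Outer tissue carried into the inner sample would hold the ratio level however strong the marker, and the slope on marker strength was 0.14 ± 0.14 (SE) in old tree 1 and -0.09 ± 0.06 in young tree 1. It was as flat in young tree 4 (-0.05 ± 0.14), where outer markers were at 10.7%. The slope thus cannot tell carry-over apart from inner bark that itself held more of these transcripts. A low outer level would also raise the percentage. The old outer-higher genes, a related set, took 4.301% of the outer counts in old tree 1. The other old trees had 5.737% to 7.257%. Their share of the inner counts was not raised in old tree 1, 2.002% against 2.012% to 2.477%. In young tree 1 they took 4.18% of outer counts (5.382% and 5.461% in the other young trees) and 2.323% of inner counts (2.064% and 2.212%).

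Inner-higher genes were less depleted in the outer bark of young trees when chosen in the other trees, with the ages weighted alike: their median outer level was 18.8% to 31.7% of the inner level in the 4 old trees and 51.2% to 57.9% in the 3 young trees (exact permutation p = 0.0286, the smallest that 35 labelings give, adjusted 0.0857 over 3 tests). The slope of each tree's inner-higher genes on the other trees was higher in all 4 old trees than in the 3 young trees, 1.18 ± 0.28 against 0.61 ± 0.03 (SD, n = 4 and 3; exact permutation p = 0.0571), while that of the outer-higher genes was 1.04 ± 0.33 against 0.86 ± 0.31 (p = 0.4857), so none of the 3 passes after adjustment. The slopes did not weight the ages alike, and a young tree was set against more old than young trees. This lowers young slopes where old ratios are larger, so the slopes are not separate support. The choice among TMM, RLE and upper-quartile scaling is argued against as the whole cause, since the gap was 1.03 log2 units with TMM and at least 0.94 ± 0.18 (SE) in the 3. Inner tissue carried into the outer sample as an even mix would put a floor under every inner marker. As the whole cause, it would put this floor at 38.4%, 33.8% and 28.6% in young trees 1, 2 and 4. Strong inner markers were at medians of 5.9%, 18% and 26.8%, with upper 95% bounds of 8.4%, 21.4% and 66.8%. These bounds are over marker genes within a tree, which are not independent. Below the floor lay all 11 markers in tree 1, all 25 in tree 2 and 25 of 39 in tree 4, whose markers fell on both sides. Carry-over of an even mix as the whole cause is thus argued against in trees 1 and 2. In tree 4 it cannot be told apart by the bound of the median. Inner bark held phloem and vascular meristem, and carry-over of only one of these would leave markers of the other without a floor. That case was not tested and stays open. A difference with stem age also stays open, untested apart from the trees.

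Other splits of the libraries were compared with the real groups. In old stems 1 of 35 splits, the real one, gave as many as 2871 genes, and the highest other gave 24. Most of these splits ignore the pairing of the layers. Only 8 splits part all 4 pairs, too few for a share below 0.05, and the others of these gave at most 0 genes. The real split alone gave as many genes for age in outer bark (6093 genes, 1 of 35 splits, highest other 293). The same held for age in inner bark (8048, 1 of 35, highest other 1335) and the blocked interaction (2840, 1 of 35, highest other 773). A share of 1 in 35 is the smallest possible and was not adjusted over the comparisons, so it does not exclude chance. Without the block the interaction count is 0, which all 35 splits reach by construction (highest other 0), so the splits decide nothing there. Splits were too few for a share below 0.05 in young stems (90 and 17 genes, 1 of 10 splits, highest other 0), in old stems with blocks (10861, 1 of 8, highest other 1) and in young stems with blocks (9219, 1 of 4, highest other 0).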

How the results depend on the processing

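Settings chosen after seeing the data were the block as a random effect, the settings and left-out trees of the blocked fit, and leaving out tree 1 of both ages. Of the alternatives for the main results, 121 stayed within 1.5 times the count or 1 SD, and 56 moved. For the 8 genes named in the text, over 10 gene and contrast pairs, 163 alternatives kept direction and call, 7 kept direction only and 0 reversed. Over all 16 pairs the rule for named genes chose, these were 232, 40 and 0, and the 4 genes of the young layer contrast, not named in the text, lost their call in 6, 12, 7 and 7 of 17 alternatives. The cause of each move was not tested, except that some settings use fewer libraries or genes.

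The replicate block, which pairs the layers of a tree, gave 10861 genes for old layers, 9219 for young layers and 2840 for the interaction; as a random effect (correlation 0.781 within a tree) it gave 9660, 8142 and 1384. For age, the numbers did not pair the samples (correlations from -0.13 to 0.13), and a block on them, in a fit of the 2 groups alone, gave 222 genes in outer and 1367 in inner bark, against 3779 and 5505 in that fit without the block. It ended the calls of Potri.010G002600 (adjusted p = 0.105 in outer and 0.0602 in inner bark), Potri.006G238600 (0.0534 in outer bark) and Potri.002G119300 (0.0798 in outer bark). DESeq2 gave 4509, 1297 and 42 genes for old layers, young layers and the interaction. Only the groups compared gave 1806 for old layers, 0 for young layers and 3779 for age in outer bark as above. Young layers gave 51 with RLE factors, 60 with upper-quartile factors and 27 with no filter. Without tree 1 of both ages, the counts were 5216 for old layers, 1504 for young layers, 10463 for age in outer and 13122 in inner bark. Age in inner bark kept 5210 genes at an absolute log2 fold change of at least 1. The correlation of the layer contrasts, 0.717, was 0.629 by Spearman and 0.679 without tree 1.

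Leaving out each library gave 1554 to 3439 genes for old layers, 0 to 235 for young layers, 0 to 5 for the interaction, 2715 to 7321 for age in outer bark, 4554 to 9863 in inner bark, and a correlation of 0.61 to 0.727. In the blocked fit, leaving out each tree gave 4561 to 9858 genes for young layers and 781 to 2961 for the interaction. The young layer count without the block is the least stable. Total counts were between 11944485 and 15980636, and genes with few counts were removed by the filter and not tested.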

Other observations

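The tests in this part were chosen after seeing the data. The 177 genes at least 16-fold higher in old outer bark had a median log2 fold change of 5.02 in old stems, where they were chosen, and 1.55 in young stems. With trees as blocks, 82 of them had a larger layer difference in old stems and 0 a smaller one, and 96 were higher in young outer bark. Their selection in old stems favours a larger value there. Fitted fold changes of these genes depend on the prior count, because their median inner level was at most 0.0837 CPM in the old trees and 0.0762 CPM in young tree 2. It was 1.25 CPM in young tree 1 and 0.464 CPM in young tree 4. Their median outer level was 0.488 CPM in old tree 1, 3.97 to 4.26 CPM in the other old trees, and 2.71, 0.887 and 2.27 CPM in young trees 1, 2 and 4. By tree, the median log2 ratio of outer to inner bark was 1.48 in old tree 1 and 3.91 to 4.19 in the other old trees. It was 0.89, 2.13 and 1.82 in young trees 1, 2 and 4, so old tree 1 lay within the young range.

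Genes with adjacent identifiers, which follow gene order on a chromosome, tended to share the layer contrast. Over 19474 adjacent pairs, the old layer log2 fold changes correlated at 0.131, and the highest of 1000 permutations of genes within chromosomes gave 0.026 (permutation p = 0.001, the smallest they can give). The value was 0.149 in young stems, 0.155 for age in outer and 0.154 for age in inner bark, each with permutation p = 0.001, also after adjustment over the 4 contrasts. Runs of at least 3 adjacent genes called in one direction numbered 16 in old stems, against a mean of 4 and a maximum of 11 in the permutations. Tandem copies that share reads may contribute to the 0.131, which was not tested here.

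The share of genes higher in old inner bark passed Fisher's exact test on 2 of the 19 chromosomes. On chromosome 9 they were 37 of 1208 genes tested (3.06%, odds ratio 0.58, Fisher's exact adjusted p = 0.0232) and on chromosome 11 they were 75 of 1011 (7.42%, odds ratio 1.52, Fisher's exact adjusted p = 0.0241), over 38 tests. The other 36 tests did not pass. Neighbouring genes are not independent, so these p-values are too small, and no test that allows for this was run.

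The age contrasts of the layers correlated at 0.833 across genes. Of 35 splits of the trees into groups of the same sizes, 8 gave a correlation as high, the real one included, up to 0.846. That correlation is not beyond what other groupings of the same trees gave.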
